A study of Mus musculus with 12 samples.

How the data were processed

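Total RNA from sorted splenic B cells of female C57BL/6 mice aged 10 weeks was measured on 12 Affymetrix arrays, per the labels. All mice carried the mb1-cre allele in heterozygous form, which expresses Cre recombinase in the B lineage, and had either no floxed Bcl6 allele (wild-type), 1 (heterozygous) or 2 (homozygous deletion). Follicular (FO) cells were the B220+AA4.1-CD21intCD23+ fraction and marginal zone (MZ) cells the CD21highCD23low fraction, per the labels, after magnetic depletion with antibodies that included CD43, CD11b, Gr-1 and CD3. RNA was extracted with TRIZOL and labelled with a 3' in vitro transcription kit, per the labels' protocols.

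The deposited values were log2 expression values per probe set, made with GCRMA per the submitters' processing notes; its version was not given in the sources used here. GCRMA corrects background by probe sequence, normalizes quantiles and summarises each probe set, so low values collect at a shared minimum. That minimum was 2.21262 on all FO arrays and 2.21924 on all MZ arrays, a difference that a single run over all arrays would not give. Levels set across the cell types therefore carry a possible difference between 2 normalization runs, which cannot be told apart from cell type. Contrasts of genotype within a cell type do not.

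The table held 45101 probe sets, of which 64 were hybridization and labelling controls. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932, and none was listed for 9211, controls included. Gene numbers of 34754 probe sets matched a mouse RefSeq gene table, and no symbol changed. A gene was represented by its probe set with the highest mean over the 12 arrays, which gave 18194 genes. Genes with a log2 value of 4 or more on at least 2 arrays were tested, 9307 in all.

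Arrays were grouped by cell type and genotype into 6 groups of 2. Group means were fitted in 1 model over all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which left 6 residual degrees of freedom. P-values were two-sided and adjusted over genes by Benjamini-Hochberg, with a threshold of 0.05. The labels do not say that the 2 arrays of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Values are given as group mean ± SD (n = 2) on the log2 scale, and changes as log2 differences ± standard error (SE) from the model. Where a group lies within 0.5 of the minimum, the fold depends on the background correction. Arrays at the minimum also show an SD near 0, which lowers the residual SD that all groups share. The p-values and SEs of such genes can therefore be too small.

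Contrasts over both cell types are the average of the FO and the MZ change, which 1 cell type can carry. They treat FO and MZ samples as independent, but the labels do not say whether both came from the same mice. If they did, the p-values of these contrasts can be too small. Of 32 gene lists, 24 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison. Camera was run again with an estimated correlation, under which none of the list calls in any of the 9 comparisons held. Even the marginal zone identity list did not pass between wild-type MZ and FO cells (camera adjusted p = 0.0743). Failing with an estimated correlation therefore does not show that a list was unchanged. Genes called in FO arrays alone were measured in MZ arrays alone with fry from limma, which tests whether they move on balance in the direction seen in FO, and the reverse. Its p-values were adjusted over the 2 genotype contrasts. Named genes followed a fixed rule. Bcl6 came first, with every probe set. Then came the 10 largest changes in each direction among genes past the threshold whose arrays did not overlap between the groups, for homozygous deletion against wild-type and for MZ against FO. For other contrasts the rule took the 5 largest. Of each list described, up to 4 members with the smallest p were eligible. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

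The model was tested on simulated arrays with the real means and residual SDs of the 9307 genes, 200 of them changed, in 20 simulations. For homozygous deletion against wild-type over both cell types, 90.75% of genes changed by 2 log2 units and 62.45% of those changed by 1 were recovered, and 4.40% of the calls were false. In FO alone the shares recovered were 78.35% and 37.5%, and in MZ alone 77.55% and 36.4%. Genes and arrays were drawn independently, with the same change in both cell types. These simulations therefore test neither the list calls nor the effect of structure shared between the real arrays. The shares recovered and false need not hold for the real calls. Alternatives covered the filter, the probe set rule, variance moderation, array weights, scaling, the arrays in the model, replicate numbers as a block, and each array left out in turn.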

Results

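The series profiled splenic FO and MZ B cells from mice in which 0, 1 or 2 Bcl6 alleles could be deleted in the B lineage. BCL6 is a transcriptional repressor best known for its role in germinal centre B cells, and the series title places the deletion in naive B cells. Each of the 6 groups held 2 arrays. Correlations between the 2 arrays of a group over tested genes were 0.97 to 0.98 in 5 groups and 0.944 in MZ wild-type. MZ wild-type replicate 1 had a Gapdh 3' minus 5' control difference of 6.90 log2 units, against -0.20 to 0.63 on the other arrays. Its beta-actin difference was 2.19, against 0.64 to 1.07. Results that rest on MZ wild-type are given with their value without this array where it matters.

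**Figure D1:**
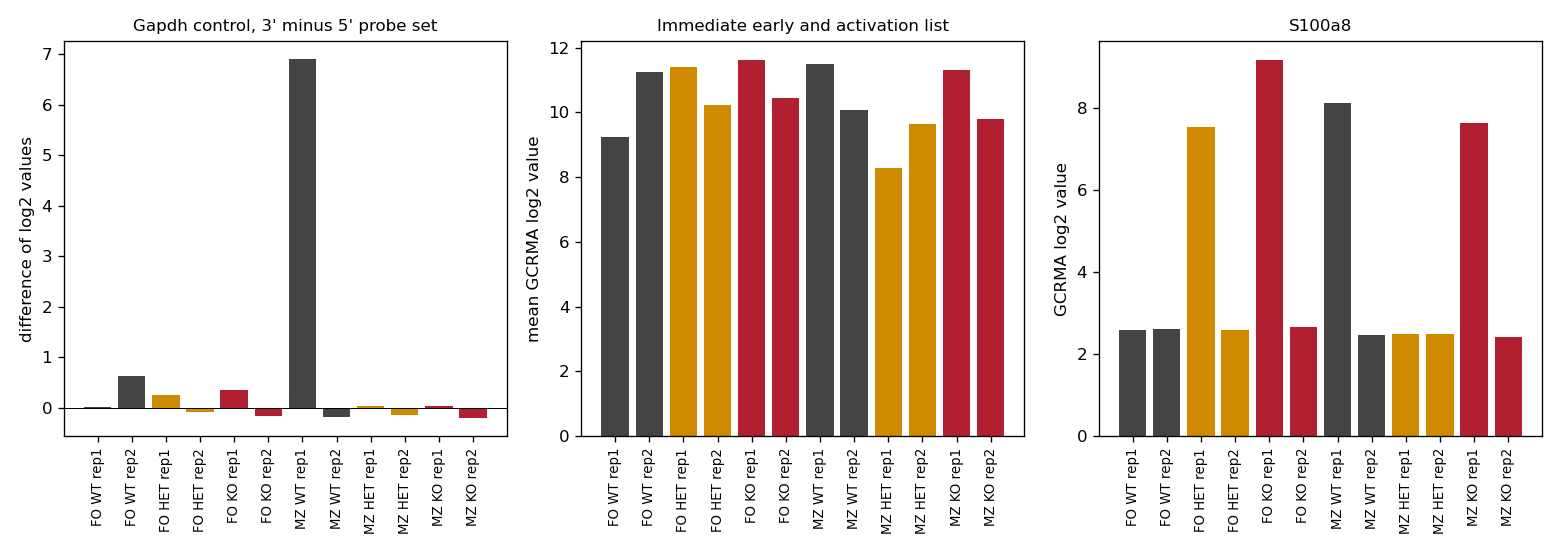
Signals per array, coloured by genotype (grey wild-type, orange heterozygous, red homozygous deletion). The left bars give the Gapdh 3' minus 5' difference in log2 units, which reached 6.90 on MZ wild-type replicate 1; the middle bars give the mean log2 value of the immediate early and activation list, from 8.28 to 11.62; the right bars give the log2 value of S100a8, which was 7.55 or more on 4 arrays and 2.66 or less on the others.

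Bcl6 itself was measured by 2 probe sets, which moved in opposite directions. The probe set with the lower signal was reduced in FO homozygous deletion arrays, at 2.42 ± 0.09 (SD, n = 2) against 5.28 ± 0.48 in wild-type and 4.89 ± 0.05 in heterozygous arrays. Its change was -2.86 ± 0.19 (SE; limma adjusted p = 0.0132 in a model over all 34958 probe sets). In every MZ array it lay at the minimum. The probe set with the higher signal, which represents the gene, was raised with homozygous deletion, at 12.79 ± 0.13 against 11.80 ± 0.21 in FO and 10.16 ± 0.30 against 8.55 ± 0.37 in MZ cells. Over both cell types it rose by 1.30 ± 0.16 (limma adjusted p = 0.0226 over the tested genes). In the model over all probe sets the adjusted p was 0.0877. The call was lost without either array of FO wild-type (adjusted p = 0.0587 and 0.0643), FO homozygous (0.0920 and 0.103), MZ heterozygous (0.0624) or MZ homozygous deletion (0.0604 and 0.0829). The exons deleted and those each probe set covers were not given in the sources used here, so neither probe set checks the genotype labels, on which the groups rest.

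**Figure D2:**
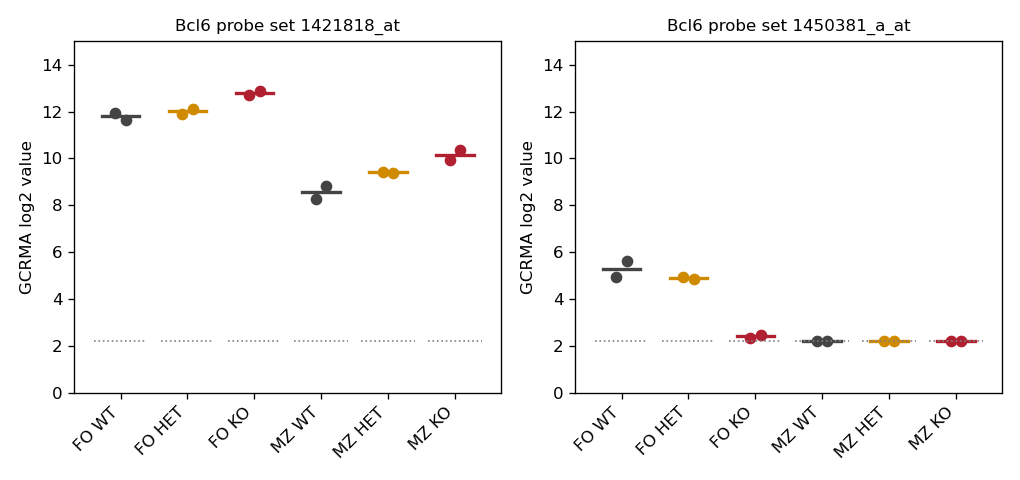
GCRMA log2 values of the 2 Bcl6 probe sets by group, with points for arrays, solid bars for group means and dotted lines for the minimum of each cell type. The probe set with the higher signal was highest in homozygous deletion arrays of each cell type, whereas the other was near the minimum in FO homozygous deletion arrays and at it in all MZ arrays.

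In the average of the FO and MZ changes, homozygous deletion raised Ackr3, Sh3bgrl2, Mgst1, Adgrl2, Upb1, Pik3r6, Klhl9, Arhgap33, Smyd2 and Pdlim1 and lowered Slc41a2, Crisp3, Chst11, Ltk, Gsn, Tspan15, Samsn1, H2-Eb2, Cd83 and Retreg1. Sh3bgrl2 showed the smallest p, from 2.67 ± 0.14 to 6.52 ± 0.09 in FO and from 2.55 ± 0.04 to 5.50 ± 0.19 in MZ cells, a mean change of 3.40 ± 0.11 (limma adjusted p = 7.30e-06). Slc41a2, a magnesium transporter, fell by 2.77 ± 0.11 (adjusted p = 1.72e-05), from 7.49 ± 0.12 to 4.48 ± 0.14 in FO and from 8.19 ± 0.02 to 5.65 ± 0.04 in MZ cells. Chst11, a chondroitin sulfotransferase, fell by 2.08 ± 0.18 (adjusted p = 0.00372). Cd83, a surface marker of activated B cells, fell by 0.96 ± 0.13 (adjusted p = 0.0253). Sh3bgrl2, Slc41a2, Chst11 and Pik3r6 kept the call without each array in turn. Cd83 lost it without any 1 of the FO wild-type, FO homozygous, MZ heterozygous and MZ homozygous arrays (adjusted p from 0.0686 to 0.118), and the other genes named here lost it without FO homozygous replicate 1, without either MZ heterozygous array and without at least 1 array more (adjusted p from 0.0505 to 0.214).

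In all, 31 genes were higher and 12 lower in this average. Of these 43, 27 had the same sign and a limma p under 0.05 before adjustment in each cell type, 13 had such a p in FO alone and 3 in MZ alone. Some of the 43 lost the call without MZ wild-type replicate 1 and other genes gained it, so a similar count there does not mean the same genes. Among the named genes, the MZ change was 0.17 for Pik3r6 (limma adjusted p = 0.857), 0.93 for Ackr3 (adjusted p = 0.883) and 0.52 for Smyd2 (adjusted p = 0.813), and the FO change was -0.17 for Tspan15 (adjusted p = 0.971), near the minimum in FO cells. The cell cycle list was higher, with a median change of 0.44, positive values in 32 of 34 members and none called alone (camera adjusted p = 2.79e-05; adjusted p = 0.702 with an estimated correlation). Without MZ wild-type replicate 2 its median was 0.0039 and the call was lost (adjusted p = 0.351); it was 0.69 without MZ wild-type replicate 1 and 0.18 without MZ homozygous replicate 1. Of 17 MHC class II presentation genes 1, H2-Eb2, fell and 15 had negative values (median -0.19, camera adjusted p = 0.00701; adjusted p = 0.702 with an estimated correlation). Adjusted over the list alone, 1 fell. The MHC class II call was lost without MZ wild-type replicate 2 (median -0.14, adjusted p = 0.306), and the median was -0.12 without FO wild-type replicate 2 or FO homozygous replicate 1 and -0.10 without MZ homozygous replicate 1. Of 14 germinal centre B cell genes Cd83 fell (2 adjusted over the list alone), and the list's median was -0.31 (camera adjusted p = 0.0108; adjusted p = 0.559 with an estimated correlation). The germinal centre call was lost without MZ wild-type replicate 1 (median -0.096, adjusted p = 0.0968) and without MZ homozygous replicate 2 (median -0.13, adjusted p = 0.0825). The count of genes was 272 without MZ wild-type replicate 2, where the array with the low 5' signal stood alone for its group, and 48 without replicate 1. It was 14 and 15 without FO wild-type replicates 1 and 2, 26 without either FO heterozygous array, 5 and 8 without FO homozygous replicates 1 and 2, 5 without either MZ heterozygous array, and 8 and 7 without MZ homozygous replicates 1 and 2.

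In FO cells, homozygous deletion raised 35 genes and lowered 5. The mean of the 2 measured erythroid markers was 8.08 and 7.90 on the FO homozygous arrays, against 9.33 and 9.74 on FO wild-type and 9.39 and 9.31 on FO heterozygous arrays. The neutrophil genes S100a8 and S100a9 were at 9.17 and 9.81 on FO homozygous replicate 1, the array with the highest immediate early mean (11.62), against 2.66 and 2.24 on replicate 2 and 2.61 or less on both FO wild-type arrays. The erythroid markers moved apart: Car2, a carbonic anhydrase, was at 4.49 ± 0.10 in homozygous against 8.32 ± 0.24 in wild-type arrays (limma adjusted p = 0.268), and Tfrc, the transferrin receptor, at 11.49 ± 0.34 against 10.75 ± 0.35 (adjusted p = 0.594). Ackr3, a scavenging chemokine receptor, went from 2.35 ± 0.00 to 11.64 ± 0.71, a change of 9.29 ± 1.08 (limma adjusted p = 0.0114). Its wild-type level was near the minimum, and its heterozygous arrays averaged 5.05 ± 2.98. Mgst1, a microsomal glutathione transferase, rose by 4.54 ± 0.51 (adjusted p = 0.0110) and Pik3r6, a regulatory subunit of phosphoinositide 3-kinase gamma, by 4.32 ± 0.17 (adjusted p = 2.34e-05). The other named genes that rose were Sspn, Sh3bgrl2, Adgrl2, Smyd2, Upb1, Nedd4 and Thyn1, by 2.91 to 4.13. Crisp3, Slc41a2, Ltk, Gsn and Chst11 fell. Gsn, which encodes the actin-severing protein gelsolin, fell by 1.92 ± 0.22 (adjusted p = 0.0114), and all 4 of its probe sets had negative values. Ackr3 lost the call without either array of FO wild-type (adjusted p = 0.0922 and 0.0776) or FO homozygous deletion (0.127 and 0.0833). Mgst1 lost it without either FO homozygous array (0.0972 and 0.0907), and Gsn without those (0.113 and 0.106) and without FO wild-type replicate 2 (0.0764). Sspn, Adgrl2, Smyd2, Upb1, Nedd4, Thyn1, Crisp3, Ltk and Chst11 lost it without either FO homozygous array (adjusted p from 0.0803 to 0.291), all of these but Smyd2 also without at least 1 FO wild-type array (from 0.0691 to 0.282), and Sspn, Nedd4, Crisp3, Ltk and Chst11 also without arrays of other groups (from 0.0604 to 0.109). Pik3r6, Sh3bgrl2 and Slc41a2 kept it without each array in turn.

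Of 28 BCL6 target genes, Ccnd2, a D-type cyclin, rose by 1.91 ± 0.28 (adjusted p = 0.0363); adjusted over the list alone, 2 rose. That list's camera adjusted p was 0.141. Ptpn22, a tyrosine phosphatase, rose by 2.02 ± 0.32 (adjusted p = 0.0427) and was the 1 of 14 members of the B1 and atypical memory list that did, with 4 adjusted over the list alone (median 0.23, camera adjusted p = 0.0343; adjusted p = 0.840 with an estimated correlation). That list lost the call without FO wild-type replicate 2 (adjusted p = 0.244) and without FO homozygous replicate 1 (median 0.0014, adjusted p = 0.196), and its median was 0.46 without FO homozygous replicate 2. Ccnd2 and Ptpn22 lost the call without any 1 of the FO wild-type, FO homozygous, MZ heterozygous and MZ homozygous arrays (adjusted p from 0.0811 to 0.291 for Ccnd2 and from 0.0717 to 0.291 for Ptpn22). Type I interferon genes had negative values in 30 of 36 members (median -0.34, camera adjusted p = 0.00253; adjusted p = 0.840 with an estimated correlation), and none passed the threshold alone. The interferon list averaged 9.54 on FO wild-type replicate 1 and 8.48 on replicate 2, and without replicate 1 its median was -0.0078 (adjusted p = 0.368), against -0.79 without replicate 2. The FO count was 14 and 17 without FO wild-type replicates 1 and 2, 26 without either FO heterozygous array, 9 and 7 without FO homozygous replicates 1 and 2, 23 without either MZ heterozygous array and 25 without either MZ homozygous array. It was 10 with the 6 FO arrays alone and the filter on low values applied again within them, an alternative chosen after seeing the data. Among the alternatives fixed beforehand, it was 0 with only the arrays of the 2 groups compared and 17 with no filter on low values.

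**Figure D3:**
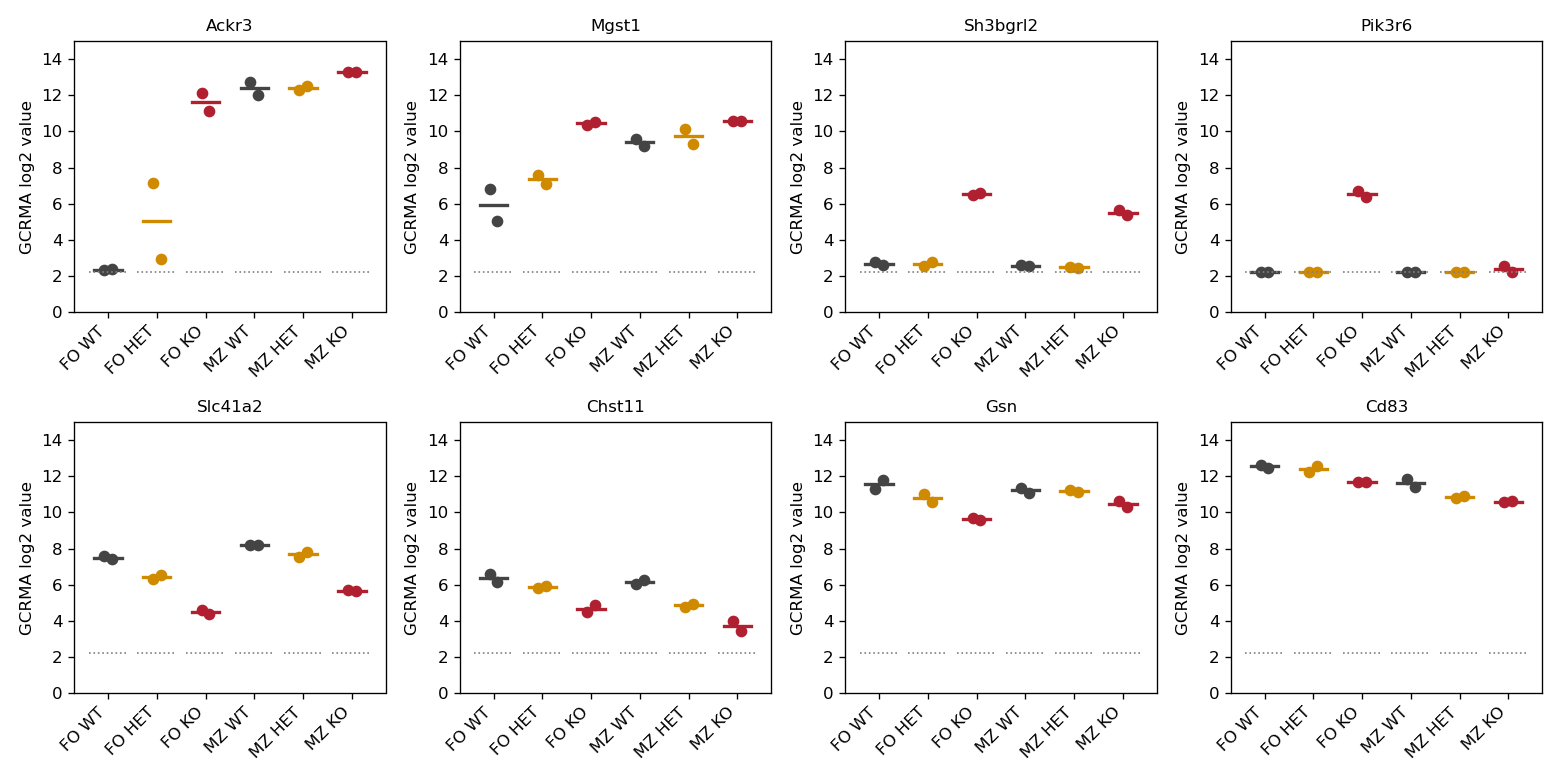
GCRMA log2 values of 8 named genes by group, with points for arrays, solid bars for group means and dotted lines for the minimum of each cell type. Ackr3 lay near the minimum in FO wild-type arrays and at 11.64 in FO homozygous deletion arrays, whereas Slc41a2 and Chst11 were lowest in homozygous deletion arrays of both cell types.

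In MZ cells, homozygous deletion raised Sh3bgrl2 and lowered Slc41a2, Chst11, Tspan15, Grip2 and Ms4a7. Sh3bgrl2 rose by 2.95 ± 0.16 (limma adjusted p = 4.21e-04). Slc41a2 fell by 2.54 ± 0.16 (adjusted p = 6.27e-04) and Chst11 by 2.45 ± 0.26 (adjusted p = 0.0172). Tspan15, a tetraspanin, fell by 2.12 ± 0.19 (adjusted p = 0.00736), from 7.55 ± 0.25 to 5.43 ± 0.01. Ms4a7 fell by 1.15 ± 0.13 (adjusted p = 0.0265). Grip2 and Ms4a7 lay near the minimum in FO cells, with FO SDs of 0.012 or less, which lowers the residual SD used for their MZ tests. Sh3bgrl2 and Slc41a2 kept the call without each array in turn. Chst11 lost it without MZ wild-type replicate 1 (0.102), MZ homozygous replicate 2 (0.0819) or any heterozygous array (adjusted p = 0.0582 or 0.0644), and Tspan15 without either MZ homozygous array (adjusted p = 0.0846 and 0.0811). Grip2 fell by 1.68 (adjusted p = 0.0172) and lost the call without any FO array (from 0.0622 to 0.0683), MZ wild-type replicate 1 (0.106) or MZ homozygous replicate 2 (0.0819). Ms4a7 lost it without any 1 array other than MZ wild-type replicate 2 (adjusted p from 0.0836 to 0.308). All 34 cell cycle genes had positive values (median 0.68, camera adjusted p = 2.54e-10; adjusted p = 0.917 with an estimated correlation), and none passed the threshold alone. Without MZ wild-type replicate 2 the cell cycle median was -0.053 and the call was lost (adjusted p = 0.465); it was 1.33 without replicate 1, 0.21 without MZ homozygous replicate 1 and 1.14 without MZ homozygous replicate 2. The count of 6 genes became 325 without MZ wild-type replicate 2, 3 without either FO heterozygous array, 2 without MZ homozygous replicate 2 and 0 with the 6 MZ arrays alone.

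The deletion effect was set side by side in the 2 cell types, which share no arrays but may share mice, since the labels do not say. Deviations from the group mean correlated between same-numbered FO and MZ arrays at 0.68 in homozygous, 0.12 in heterozygous and -0.22 in wild-type groups. If mice were shared, agreement between the cell types could reflect variation between mice, and the fry p-values could be too small. Sh3bgrl2, Slc41a2 and Chst11 were called in both by the model over all 12 arrays, which shares 1 residual SD per gene between the cell types, so the 2 lists are not independent. Of the 40 FO calls, 34 had the same sign in MZ cells and 17 of these had a limma p under 0.05 before adjustment. Over all 9307 tested genes, 56.7% of the FO and MZ changes had the same direction. With the filter over all 12 arrays kept, 5 genes were called from FO arrays alone. They had a median signed change of 2.06 in MZ homozygous deletion arrays, with 5 of 5 in the same direction (fry adjusted p = 5.95e-04). These were Pik3r6, Sh3bgrl2, Car2, Slc41a2 and Ahnak. Pik3r6 lay near the minimum in MZ cells, with a change of 0.17, and Car2 did so on all MZ arrays but 1. The median was the change of Car2, whose MZ wild-type level was 6.68 on replicate 1 and 2.49 on replicate 2; without replicate 1 the median was 2.47 and 4 of 5 had the same direction. The mean of the erythroid markers Car2 and Tfrc was 8.77 on that array, which had the low 5' signal, and 6.23 to 6.61 on the other MZ arrays. This mean contains Car2 itself, so it gives no separate sign of erythroid cells. With the filter on low values applied within each cell type, an alternative chosen after seeing the data, 3 genes were left, with a median of 2.54 (fry adjusted p = 3.65e-04). For the 100 genes with the smallest p in FO arrays the median was 0.41, with 80 of 100 in the same direction (fry adjusted p = 0.0674), and without MZ wild-type replicate 1 it was 0.50, with 87 of 100 (adjusted p = 0.0415). In MZ heterozygous arrays the 5 genes had a median signed change of 0 (fry adjusted p = 0.432; 0.00862 without MZ wild-type replicate 2). That 0 was Pik3r6, at the minimum on all MZ wild-type and heterozygous arrays, and the other signed changes ran from -1.72 for Ahnak to 2.05 for Car2, so the median does not show that heterozygous arrays were unchanged. No gene passed the threshold from MZ arrays alone. The 100 genes with the smallest p there had a median signed change of 0.41 in FO homozygous arrays, with 83 of 100 in the same direction (adjusted p = 2.04e-04), and of 0.075 in FO heterozygous arrays, with 62 of 100 (adjusted p = 0.0169), against 51.6% of all tested genes. The reverse did not pass for heterozygous arrays. The 100 genes picked in FO arrays had a median signed change of -0.055 in MZ heterozygous arrays (fry adjusted p = 0.752). Of these, 40 of 100 had the same direction, against 41.2% of all tested genes.

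Of the effect's difference between cell types, 1 gene passed the test, with 348 genes at a limma p under 0.05 before adjustment, where chance gives 465. Pik3r6 changed by 4.15 ± 0.24 log2 units less in MZ than in FO cells (MZ minus FO -4.15, limma adjusted p = 6.92e-04). It was at the minimum in wild-type and heterozygous arrays of both cell types, at 6.53 ± 0.25 in FO homozygous arrays and at 2.39 ± 0.24 in MZ homozygous arrays. Ackr3 did not pass this test (MZ minus FO -8.36 ± 1.53, adjusted p = 0.278). The count was 107 without MZ wild-type replicate 2, and 2 without MZ wild-type replicate 1 or any 1 of the FO wild-type and FO heterozygous arrays.

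Deletion of 1 allele was tested against wild-type. In FO cells 0 genes passed with limma, and 184 had p under 0.05 before adjustment, where chance gives 465. In MZ cells only Grip2, a glutamate receptor interacting protein, passed and fell by 1.87 ± 0.18 (adjusted p = 0.0368), from 6.19 ± 0.03 to 4.32 ± 0.21. The MZ count was 0 with a replicate block and with the 6 MZ arrays alone. Grip2 lost the call, and the count was 0, without MZ wild-type replicate 1 (adjusted p = 0.457), either MZ heterozygous array (0.595 and 0.198) or any FO array (from 0.148 to 0.161). The MZ count was 415 without MZ wild-type replicate 2, and the FO count 1 without FO wild-type replicate 2. Over both cell types 0 genes passed, with 124 at p under 0.05 before adjustment and 79 calls without MZ wild-type replicate 2.

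Some gene lists passed camera at the preset correlation between heterozygous and wild-type arrays, and none with an estimated correlation, with no member of those described called. In MZ cells the immediate early and activation list had a median of -1.89 with negative values in 29 of 31 members (camera adjusted p = 6.24e-08; adjusted p = 0.699 with an estimated correlation). The mean of this list differed by 1.40 between the 2 MZ wild-type arrays and by 1.37 between the 2 MZ heterozygous arrays. The neutrophil gene S100a8 was at 8.11 and 2.46 on MZ wild-type replicates 1 and 2 and at 2.50 on both MZ heterozygous arrays. The MZ cell cycle list had a median of -0.86 (camera adjusted p = 1.58e-04; adjusted p = 0.809 with an estimated correlation), with the call lost without MZ wild-type replicate 1 (median -0.055, adjusted p = 0.946) and MZ heterozygous replicate 2 (median -0.67, adjusted p = 0.0561), and a median of -1.58 without MZ wild-type replicate 2. The immediate early median was -0.92 without MZ wild-type replicate 1 and -1.02 without MZ heterozygous replicate 1. In FO cells 33 of 36 type I interferon genes had negative values (median -0.43, camera adjusted p = 3.56e-09; adjusted p = 0.930 with an estimated correlation), and the median was 0.029 without FO wild-type replicate 1 (adjusted p = 0.704) and -0.95 without replicate 2.

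In the average of the cell types, homozygous against heterozygous deletion raised Sh3bgrl2, Adgrl2, Pik3r6, Plxna1 and Il18 and lowered Slc41a2. The Pik3r6 value came from FO cells, at 6.53 ± 0.25 against 2.21 ± 0.00, with 2.39 ± 0.24 against 2.22 ± 0.00 in MZ cells. Il18, an inflammatory cytokine, rose by 1.22 ± 0.13 (limma adjusted p = 0.0202), with 10.37 ± 0.19 against 8.85 ± 0.05 in FO and 10.04 ± 0.10 against 9.12 ± 0.17 in MZ cells. Plxna1, a semaphorin receptor, rose by 1.70 ± 0.20 (adjusted p = 0.0342). Il18 lost the call without any 1 of the heterozygous and homozygous arrays (adjusted p from 0.0703 to 0.139), and Adgrl2 and Plxna1 without these or either FO wild-type array (from 0.0672 to 0.213). All 34 cell cycle genes had positive values (median 0.83, camera adjusted p = 1.73e-16; adjusted p = 0.570 with an estimated correlation), with 0 called alone, and the median was 0.52 without MZ homozygous replicate 1. The glycolysis list had a median of 0.19 over 17 genes (camera adjusted p = 0.00430, and 0.653 with an estimated correlation). The immediate early and activation list was higher too, with a median of 0.79. S100a8 was at 9.17 and 2.66 on FO homozygous and 7.55 and 2.60 on FO heterozygous arrays. In MZ cells it was at 7.63 and 2.42 on homozygous and 2.50 on both heterozygous arrays. The split of 5 higher and 1 lower became 4 and 2 after quantile normalization, and the count was 14 without either MZ wild-type array. It was 3 without FO heterozygous replicate 2, FO homozygous replicate 1, either MZ heterozygous array or MZ homozygous replicate 1.

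MZ and FO cells of wild-type mice differed in 2066 genes, 993 higher and 1073 lower in MZ. The named genes higher in MZ cells were Ackr3, Tsga13, Tbc1d9, Nebl, Ackr2, Plxnd1, Pla2g7, Rundc3b, Asb2 and AF067061, by 6.24 to 10.03. Those lower were Crisp3, Wfdc17, Mapk12, Gm11346, Fcgrt, Kctd14, Mex3b, Dpm3, Sdc1 and Gpr146. Of 22 marginal zone identity genes 17 rose and none fell (19 adjusted over the list alone), including Cd9, a tetraspanin, at 11.92 ± 0.07 against 7.18 ± 0.04 (median of the list 2.36, camera adjusted p = 1.71e-14; adjusted p = 0.0743 with an estimated correlation). Of 15 follicular identity genes 9 fell (10 adjusted over the list alone), including Fcer2a, which encodes the CD23 used in the sort, at -4.54 ± 0.27 (median -1.64, camera adjusted p = 1.26e-06; adjusted p = 0.170 with an estimated correlation).

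Of 34 cell cycle genes 17 rose and 1 fell (24 and 1 adjusted over the list alone; median 2.15, camera adjusted p = 8.54e-09; adjusted p = 0.475 with an estimated correlation). The list averaged 8.63 on MZ wild-type replicate 1 and 7.18 on replicate 2, and without replicate 1 its median was 1.59 (camera adjusted p = 2.61e-06). Tk1, thymidine kinase, rose by 2.26 ± 0.29 (adjusted p = 7.52e-04). Of 28 BCL6 target genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; median 1.03, camera adjusted p = 0.00388; adjusted p = 0.475 with an estimated correlation), and the median was 0.40 without FO wild-type replicate 1 and 0.55 without MZ wild-type replicate 1. Prdm1, a regulator of plasma cell differentiation, rose by 4.24 ± 0.37 (adjusted p = 9.91e-05). The median of all tested genes was -0.12, and the split became 1167 higher and 841 lower after median centring and 1099 and 673 after quantile normalization. The count was 1307 without FO wild-type replicate 2, and the apparent separate normalization of the cell types lies on top of each of these values.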

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

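The effect of homozygous deletion on Pik3r6 differed between the cell types, with a difference of -4.15 (MZ minus FO, limma adjusted p = 6.92e-04), and the call held in all 24 alternatives run. Its SD was 0 in the wild-type and heterozygous groups of both cell types, which lay at the minimum and cannot show their spread. The p-value can therefore be too small, and the alternatives rest on the same values. The effect on the BCL6 target gene list differed, with a median of -0.63 over 28 genes (camera adjusted p = 0.0108; adjusted p = 0.981 with an estimated correlation). It was -0.19 without MZ wild-type replicate 1 (adjusted p = 0.0665). It was -0.32 without FO homozygous replicate 1 (adjusted p = 0.160), -0.32 without FO wild-type replicate 1, -1.12 without MZ wild-type replicate 2 and -0.30 without MZ homozygous replicate 2 (adjusted p = 0.249). The effect on the cell cycle list differed, with a median of 0.48 over 34 genes (camera adjusted p = 4.50e-05; adjusted p = 0.981 with an estimated correlation). It was -0.33 without MZ wild-type replicate 2 (adjusted p = 0.756) and -0.050 without MZ homozygous replicate 1 (adjusted p = 0.172). The call held at 0.78 without FO wild-type replicate 2, 0.77 and 0.28 without FO homozygous replicates 1 and 2, 1.20 without MZ wild-type replicate 1 and 0.93 without MZ homozygous replicate 2.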

How the results depend on the processing

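Chosen after seeing the data were these alternatives: numbers of FO wild-type crossed, a replicate block separate in each cell type, the 6 arrays of a cell type alone, and the settings of the FO calls measured in MZ other than the smallest 100 p and no filter. Counts are given for homozygous deletion against wild-type unless named. Where a count moved, the cause was not tested unless stated. With no filter, counts were 17 in FO, 13 over both, 6 for the difference, 1, 5 and 1 for heterozygous against wild-type in FO, in MZ and over both, 8089 for MZ against FO, and 69 list calls against 39. No gene was then picked from FO arrays alone, so that result had no value. With no filter, any gene at the minimum on all arrays entered the MZ against FO test with an SD of 0. Its value still differed, as the minimum was 2.21262 in FO and 2.21924 in MZ arrays. The 8089 therefore cannot be read as a count of cell type differences. With each probe set separate, counts were 3 in MZ, 14 over both and 0 for heterozygous MZ. With trend and robust moderation, and after quantile normalization, heterozygous MZ gave 0. Array weights gave 3 in MZ, 0 for heterozygous MZ, 27 for homozygous against heterozygous and 1320 for MZ against FO. With only the groups compared, and so fewer samples, counts were 0 in FO, 0 in MZ, 5 over both, 2 for the difference, 0 for heterozygous MZ, 11 for homozygous against heterozygous and 604 for MZ against FO. The 6 arrays of a cell type alone, with the filter applied again within them, gave 10 in FO, 0 in MZ and 0 for heterozygous MZ. MZ against FO averaged over genotypes gave 4137. A log2 change of 1 as a further threshold kept counts within 1.5 times.

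Replicate numbers were not shown to pair samples across all groups. Deviations of same-numbered arrays correlated over 0.1 in 8 of 15 pairs of groups and under -0.1 in 4, from -0.26 to 0.77. Every pair among FO heterozygous, FO homozygous, MZ wild-type and MZ homozygous arrays lay at 0.45 to 0.77. The pairs under -0.1 all held FO wild-type, which correlated at 0.58 with MZ heterozygous arrays. The samples thus share a structure that the main model has no term for. The replicate block gave 61 genes in FO, 67 over both, 0 for heterozygous MZ and 10 for homozygous against heterozygous, and 51 list calls. A separate replicate block in each cell type gave 3 in MZ, 21 over both and 0 for heterozygous MZ; crossed FO wild-type numbers gave 49 in FO and 0 for heterozygous FO. Leaving out each array in turn, which assumes that a lone array varies like the other groups, gave 7 to 58 in FO, 2 to 325 in MZ, 5 to 272 over both, and 1 to 107 for the difference. It gave 0 to 1, 0 to 415 and 0 to 79 for heterozygous deletion in FO, in MZ and over both, 3 to 14 for homozygous against heterozygous, 1307 to 2537 for MZ against FO, and 37 to 52 list calls. The highest MZ, both and difference counts came without MZ wild-type replicate 2. It gave a median of FO calls in MZ arrays of 2.06 to 2.55 for homozygous and -0.036 to 0 for heterozygous arrays. The latter passed fry without MZ wild-type replicate 2, at 0, and with the mean of probe sets, at 0.26; the former did not pass with the 100 smallest p, at 0.41. The estimated correlation left 0 list calls. Lists, and FO calls in MZ arrays, were not run with each probe set separate.

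Of 3501 alternatives over 145 gene results, those of list members past the threshold included, 2823 kept the call, 675 lost it and 3 reversed. Bcl6 over both cell types was at -0.065 with the mean of its probe sets and -1.43 with each separate, where the probe set with the smallest p was the one that fell, and by the same rule Cflar was at 0.96 for MZ against FO. Of 795 over 39 list results, 677 kept the call, 113 lost it and in 5 the direction of camera's test reversed. The median itself changed sign in 6, all with an array left out, and in each of these the call was lost. In 5 of them camera's direction stayed the same. These 5 were the MZ cell cycle list (-0.053) and oxidative phosphorylation list (-0.032) without MZ wild-type replicate 2, the latter without MZ homozygous replicate 1 (-0.016), and the cell cycle list's difference between MZ and FO with each of these left out in turn (-0.33 and -0.050). Camera's direction reversed without FO wild-type replicate 1 for the type I interferon list, at -0.0078 in FO and -0.10 over both, and at 0.029 for heterozygous FO, and for the heterozygous FO interferon gamma and MHC class I list, at -0.055. Without replicate 2 these were at -0.79, -0.37, -0.95 and -0.44. The heterozygous MZ cell cycle list was at -0.055 without MZ wild-type replicate 1, where camera's direction reversed, and -1.58 without replicate 2.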

Other observations

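The tests of the Bcl6 pattern and that of variation between arrays of a group were chosen after the results were seen. Of markers of cell types that the sort should exclude, and of sex-linked genes, the measured members were 3 of 19 T cell, 1 of 14 NK, 4 of 16 neutrophil, 2 of 16 erythroid, 4 of 16 dendritic, 1 of 14 platelet, 1 of 18 stromal and 2 of 7 sex-linked genes, too few to test as lists. The highest mean over the 12 arrays was 12.82 for a dendritic marker, Irf8, which B cells also express, 10.82 for an erythroid marker, Tfrc, and 9.16 for the stromal and endothelial marker Pecam1. It was 6.83 for T cell, 4.40 for neutrophil, 4.15 for platelet and 3.76 for NK markers. Whether the signals of any of these markers, Tfrc and Pecam1 included, came from cells other than B cells was not tested. The macrophage and monocyte list, with 10 members, did not pass in any of the 9 comparisons (camera adjusted p 0.123 or more). The neutrophil genes S100a8 and S100a9, although the depletion included Gr-1 and CD11b, were high on FO heterozygous replicate 1 (7.55 and 7.94), FO homozygous replicate 1 (9.17 and 9.81), MZ wild-type replicate 1 (8.11 and 7.93) and MZ homozygous replicate 1 (7.63 and 7.04). S100a8 was at 2.66 or less on the other arrays. The immediate early list averaged 11.30 to 11.62 on those 4 arrays, and 11.25 or less on the rest. Probe sets without a single gene symbol gave 0 calls of 3189 tested in each genotype comparison, and 188 higher and 235 lower for MZ against FO. Across genes, which are not independent, homozygous deletion effects in FO and MZ cells correlated at Pearson r = 0.25, and heterozygous effects at -0.33.

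The 2 Bcl6 probe sets moved in opposite directions with homozygous deletion. Scaling differences left in the deposited values are argued against, since the rise of the probe set with the higher signal was 1.32 or more after centring and after quantile normalization. GCRMA had already normalized quantiles, so these steps could move the values little. They cannot test an effect of the GCRMA step itself. Release of repression by BCL6 of its own gene may contribute and stays open: heterozygous arrays were 0.53 ± 0.16 higher than wild-type (limma adjusted p = 1). Swapped labels stay open too: the other probe set changed by -2.86 in FO cells, which argues against a swap only if it reads the deleted exons, whose positions were not given. For the same reason, whether the rising probe set reads a transcript that lacks these exons was not tested.

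The activation list was lower in heterozygous than in wild-type MZ arrays. Without MZ wild-type replicate 1, the array with low 5' signal, the median was -0.92 against -1.89 with it, still called at the preset correlation (camera adjusted p = 2.85e-07), so that array may account for part of it. With all arrays and an estimated correlation the list was not called (adjusted p = 0.699). Variation between arrays of 1 group stays open: the list mean differed by 2.01 between the 2 FO wild-type arrays, but by 1.40 and 1.37 in the 2 groups compared, and in none of the other 5 groups by as much as the heterozygous minus wild-type difference of -1.82. Genotype stays open too, but homozygous deletion showed no fall of that size. The list mean was 11.30 and 9.80 on MZ homozygous replicates 1 and 2. It was 11.49 and 10.08 on MZ wild-type and 8.28 and 9.64 on MZ heterozygous replicates 1 and 2.

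Of the 35 genes raised in FO homozygous arrays, 21 were higher in MZ than in FO heterozygous arrays. Marginal zone B cells within the sorted FO fraction are argued against only as the source of the Ackr3 rise. To bring Ackr3 to its level, 31.4% of cells would be needed, which would raise the 50 genes with the largest MZ over FO difference by a median of 3.21. Their median change was 0.029, with quartiles of 0 and 0.69. A smaller share of these cells, which could raise other genes, was not tested and stays open. The test also set FO against MZ levels, which were apparently normalized separately. A low starting level stays open, since the raised genes' median MZ minus FO difference of 0.23 exceeded that of 88.95% of 10000 random lists matched on FO level.

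Other splits of the 8 arrays into groups of 4 were fitted with cell type as a term, 34 of which could be estimated. For homozygous deletion against wild-type the real split gave 2 genes, 3 of the 34 splits, the real one included, gave as many, and the highest other gave 14, so chance was not excluded for this count in that model. That split set FO wild-type replicate 1, FO homozygous replicate 2, MZ wild-type replicate 2 and MZ homozygous replicate 2 against the others, the array with the lower immediate early mean in each group, and points to a structure of the samples. For heterozygous deletion against wild-type the real split gave 0, as did all 34 splits. For homozygous against heterozygous the real split gave 6 genes and the highest other 0, so only 1 of the 34, the real one, gave as many. That is the smallest share 34 splits can give, in 1 of 3 such tests. Labels were also exchanged between FO and MZ arrays, and splits uneven over the cell types overlap with the cell type term. Chance is therefore not excluded for this comparison either.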
